A study of Mus musculus with 6 samples.

How the data were processed

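Total RNA was extracted from mouse hearts at 1 month of age with TRIzol and sequenced on Illumina libraries, per the labels' protocols. The 6 libraries are 3 controls with floxed Txn1 alleles (replicates 3, 4 and 5) and 3 with the same alleles and a Cre transgene driven by Myh6 (replicates 6, 7 and 8). The deposited table gives, per the file headers, log2 CPM (counts scaled to library size) for 14133 genes with 1 column per library. Per the submitters' processing notes the reads were aligned to mm10, and CASAVA, HISAT2 and edgeR are named without versions or order. The names of the deposited table refer to RefSeq NM transcripts. No filter on genes is stated.

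The deposited values were checked against their unit. All 6 libraries share a floor of -3.29 log2 CPM, so a pseudocount had been added before deposit. CPM summed to 1017500 to 1044060 in the controls and 921199 to 1001290 in the libraries with Cre. The library sizes behind the values were therefore not the plain sums of reads, and the sums differed by group. Steps above the floor gave each library's CPM per read, and from it the reads per gene. Of 7465 genes with 1 NM transcript, 7455 had whole reads in all 6 libraries within a tolerance of 0.002 reads, and 3926 of 6387 genes with more transcripts had fractions. Among the 3936 genes with fractions, the number of NM transcripts was a multiple of the fraction's denominator in 91.4%, against at most 43.2% in 1000 permutations of the transcript numbers among them. A gene's value is therefore read here as reads averaged over transcripts. 66 genes had values identical to those of another gene, and 5 lay at the floor in all 6 libraries. Per library 185 to 519 genes lay at the floor. Coordinates are those of GRCm38, the assembly of mm10, counted from 1.

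Genes with a mean of at least 0 log2 CPM over the 6 libraries were tested (12516, with 1617 left out). The test was limma 3.58.1 in R 4.3.3, a group-means model on the deposited log2 values with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are labelled knockout minus control, given with the SE of the fit, and group means with the SD of 3 libraries. Rose and fell are used for genes past that threshold. The fit has 4 residual degrees of freedom and takes the same spread for both groups. In simulated libraries of the same 12516 genes with 200 changed genes, 6%, 54%, 84% and 96% were recovered at log2 changes of 0.5, 1, 2 and 3, with 5 false among 125 calls. The simulated genes were independent and had the same spread in both groups. The deposited libraries differ from that, so these rates may not hold for them. Among pairs of control libraries the variance of reads was 7.96 to 8.71 times that of counting error (chi-square per gene). Among pairs labelled knockout it was 23.6 to 48.1 times.

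Gene lists were tested with camera and a preset correlation of 0.01, beside an estimated correlation, and with fry, which tests whether a list's genes move 1 way on balance and does not compare them with other genes. The 43 lists were complex I, complexes II and III, complex IV, ATP synthase, TCA cycle, fatty acid oxidation, mitochondrial biogenesis regulators, mitochondrial ribosome, cytosolic ribosome, mTOR pathway, ATF4 targets, mitochondrial stress response, ER unfolded protein response, heat shock response, NRF2 targets, thioredoxin and glutaredoxin systems, fetal and hypertrophy genes, adult cardiomyocyte genes, cardiac transcription factors, atrial genes, extracellular matrix and fibrosis, fibroblasts, endothelial cells, smooth muscle and pericytes, macrophages, lymphocytes, neutrophils, erythroid cells, adipocytes, epicardium and nerve, skeletal muscle, cell cycle, p53 targets, apoptosis and cell death, autophagy and lysosome, proteasome and atrogenes, glycolysis, cholesterol and lipid synthesis, interferon response, inflammation, immediate early genes, circadian clock and hypoxia response. Lists overlap in some genes. Members were also adjusted over the list alone. The table of lists, the tests, the filter and the rule for named genes were fixed before the data were examined. That rule took Txn1, the 12 largest changes in each direction among genes past the test with a mean of at least 2 log2 CPM and no overlap, up to 4 members per list with the smallest p, further members past the test with at least 2-fold changes, and 12 genes of interest. It gave 231 genes, and the text names a part of them picked after their values were seen. Some results for single genes are not reported here. Atpif1, Slc38a2, Sod2, Pfkp, Pfkm, Slc2a4, Tef, Nr1d1 and Morf4l1b lie outside it and were chosen after their values were seen, as were genes named with the stretch of chromosome 13 that lie outside it.

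The alternatives were no filter, a mean of at least 3, median-centred libraries, quantile normalization, log2(CPM + 1), no trend, a robust trend, library weights, a threshold of 0.01, at least 1.5-fold, and each library left out. limma-voom on the recovered reads was added after the data were seen. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.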

Results

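RNA from hearts of C57BL/6 mice at 1 month of age was sequenced to ask what loss of thioredoxin-1, the product of Txn1, changes in the heart, with mitochondrial function and mTOR signalling named in the title of the series. Thioredoxin-1 is a small protein that reduces disulfide bonds in other proteins. The 6 libraries form 2 groups of 3. The control hearts carried floxed Txn1 alleles without Cre (replicates 3, 4 and 5), and the others carried the same alleles with Cre recombinase driven by Myh6, a promoter active in cardiomyocytes (replicates 6, 7 and 8). The reads recovered from the deposited values came to 13705281, 9257984 and 10314636 in the control libraries and 8961708, 10236783 and 8347636 in the others. Nothing in the labels states that the replicates were separate animals, so each p measures the spread between these samples.

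Txn1 RNA was not lower in the libraries labelled knockout. Its values were 6.640, 6.996 and 7.042 log2 CPM in control replicates 3, 4 and 5, and 6.950, 6.902 and 7.132 log2 CPM in replicates 6, 7 and 8 (means 6.89 ± 0.22 and 6.99 ± 0.12, SD, n = 3 each). The log2 difference was 0.10 (95% confidence interval -0.22 to 0.42, limma adjusted p = 0.72), and an exact two-sided permutation test gave p = 0.7, where the smallest p that 3 against 3 allows is 0.1. Txn1 lies on chromosome 4, 57943373 to 57956411 (mm10, annotated as GRCm38). The value covers the whole gene, which exons are floxed is not given in the sources used here, and RNA of cells other than cardiomyocytes was in the same libraries. The value therefore does not show whether the labels are right, and a wrong label is not excluded by it. Without control replicate 3 the difference was -0.025. Because the targeted gene was not lower, the second group is called the libraries labelled knockout throughout, and every direction is that of labelled knockout minus control.

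Hearts labelled knockout had far more RNA of natriuretic peptide genes and of many matrix genes and less RNA of many respiratory chain genes than control hearts. Nppa, the atrial natriuretic peptide gene, went from 8.52 ± 0.82 to 13.74 ± 1.00 log2 CPM (SD, n = 3), a 37.4-fold difference, and Ankrd1, a stress-responsive sarcomere gene, rose 11.7-fold. Clcn1, a chloride channel gene, fell by 4.44 on the log2 scale and Rpl3l, which encodes the muscle form of ribosomal protein L3, fell by 3.51. Of 12516 tested genes, 1209 (9.66%) passed an adjusted p under 0.05 (limma with a trend, Benjamini-Hochberg), 600 higher and 609 lower. At least 2-fold differences were found for 374 of the genes that rose and 222 of those that fell. The median log2 fold change was 1.14 among the genes that rose, -0.85 among those that fell and -0.01 over all tested genes. The 3 values of 1 group lay wholly above or below those of the other in 1204 of the 1209 genes, which largely follows from the test. The same held for 30.7% of all tested genes, where chance gives 10% on average, and the difference was not tested.

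The count depended on the libraries. It was 526, 403 and 417 without control replicate 3, 4 or 5, 992 and 703 without replicate 6 or 7 and 2185 without replicate 8. Without the trend in the variance it was 121. Of the 146 genes named in the text as past the test, 76 stayed past it with any 1 library left out.

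**Figure D1:**
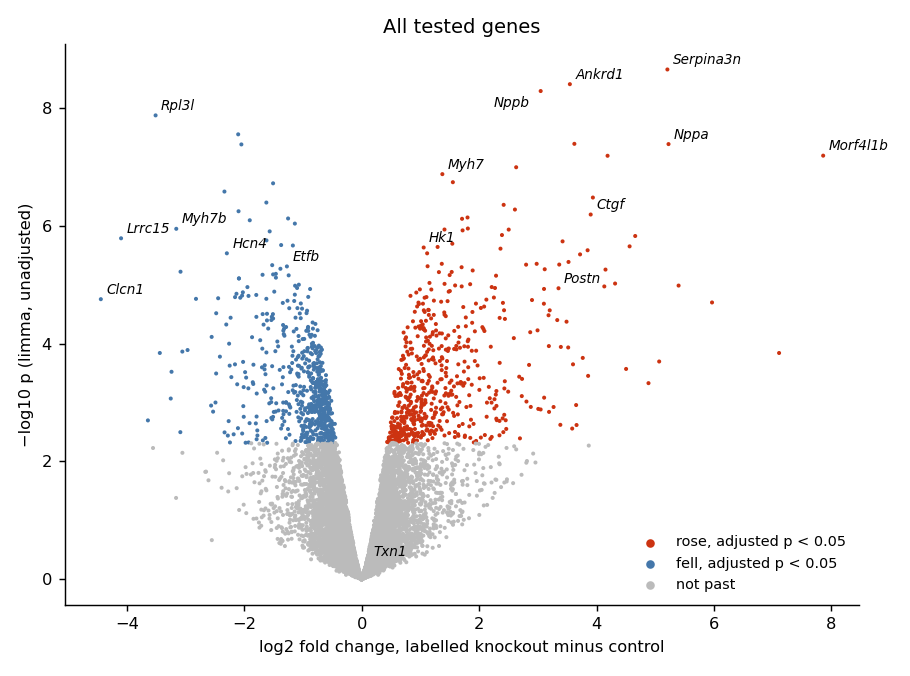
Log2 fold change (labelled knockout minus control) against the negative log10 of the unadjusted limma p for the 12516 tested genes, 1 point per gene. The 600 genes that rose (red) reach higher log2 fold changes than the 609 that fell (blue) reach downward, and Txn1 lies near 0 among the grey genes that were not past the test.

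The 3 control libraries lay close together on the first principal component, which held 49.0% of the variance, with scores of -32.1, -39.2 and -36.1. The libraries labelled knockout lay at 41.3, 57.5 and 8.58 for replicates 6, 7 and 8. In replicate 8, 899 of the 1209 genes moved less from the control mean than in both other libraries of its group, against 232 for replicate 6. Myh6, the gene of the main adult myosin heavy chain, took 6.45%, 6.49% and 6.99% of the reads in the control libraries and 3.71%, 4.23% and 5.57% in replicates 6, 7 and 8. Replicate 6 also had 266 genes more than 1 log2 unit above every other library, while the other libraries had 43 to 122.

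**Figure D2:**
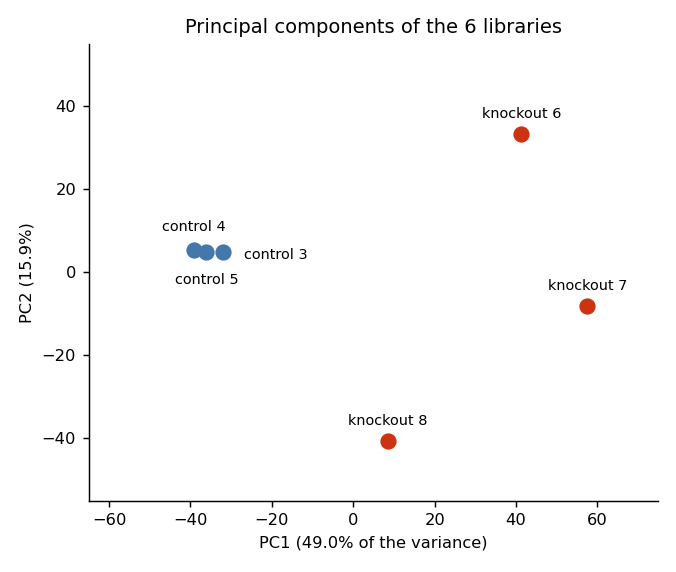
Scores of the 6 libraries on the first and second principal components (49.0% and 15.9% of the variance) of the log2 CPM of all tested genes, blue for control and red for labelled knockout. The controls lie together, and replicate 8 lies nearest to them on the first component, at 8.58.

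Among genes past the test with a mean of at least 2 log2 CPM and no overlap between the groups, the largest increases included Nppa, Serpina3n, Wisp2, Ltbp2, Krt18, Grin2c, Thbs4, Lrp8, Nmrk2, Ctgf and Cilp. Serpina3n, an acute-phase protease inhibitor of a family of similar genes whose reads are hard to separate, rose 36.9-fold (from 2.22 ± 0.30 to 7.42 ± 0.87 log2 CPM, adjusted p = 2.2e-05). Ctgf and Wisp2, both of the CCN family of matrix-associated proteins, rose by 3.90 ± 0.42 and 4.66 ± 0.55 (log2, SE). Nmrk2, a nicotinamide riboside kinase of muscle, rose 15.3-fold, Grin2c, a glutamate receptor subunit, 18.2-fold, and Lrp8, a lipoprotein receptor, 17.5-fold. Krt18, an epithelial keratin, rose 19.9-fold from 0.64 ± 0.62 log2 CPM. Ltbp2, Thbs4 and Cilp, which encode matrix proteins, rose 23.6-fold, 17.8-fold and 14.4-fold. Thbs4 lost its call in 2 settings, among them a robust trend (adjusted p = 0.058). Ltbp2, Krt18, Lrp8 and Cilp each lost the call in 1 setting (adjusted p = 0.051, 0.056, 0.051 and 0.052).

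By the same rule the 12 largest decreases were in Clcn1, Lrrc15, Rpl3l, Ces1d, Myh7b, Klhl33, Mylk4, Dnaaf3, Scn4a, Kcnj3, Smco1 and Slc36a2, with log2 fold changes of -4.44 to -2.34. Rpl3l went from 8.47 ± 0.08 to 4.96 ± 0.73 log2 CPM (SD, n = 3, adjusted p = 4.2e-05). Myh7b, a myosin heavy chain gene, fell by 3.16 on the log2 scale (adjusted p = 4.9e-04), and Mylk4, a myosin light chain kinase, by 2.82. Kcnj3, which encodes a subunit of the acetylcholine-gated potassium channel, and Scn4a, a voltage-gated sodium channel gene, both fell by 2.48. Klhl33, Dnaaf3 and Smco1 fell by 3.09, 2.56 and 2.45, and Slc36a2, an amino acid transporter gene, by 2.34. Lrrc15 fell by 4.10, and Ces1d, a carboxylesterase gene, by 3.24. Calls lost without 1 library were those of Ces1d (without control 5, adjusted p = 0.064) and Scn4a (without controls 3 or 4, adjusted p up to 0.057). Ces1d was also not past the test with a robust trend (adjusted p = 0.15). Clcn1, Mylk4, Dnaaf3 and Kcnj3 each lost the call in 1 setting that kept all libraries (adjusted p = 0.057, 0.063, 0.068 and 0.061).

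Of 25 tested genes known to be raised in the stressed or hypertrophic heart, 16 rose in the libraries labelled knockout. Besides Nppa and Ankrd1, Nppb, the gene of B-type natriuretic peptide, rose 8.27-fold (from 7.10 ± 0.22 to 10.15 ± 0.51 log2 CPM, SD, n = 3), Acta1, the skeletal form of actin, 5.34-fold, and Myh7, the beta myosin heavy chain of the fetal ventricle, 2.59-fold. Des and Fhl1, which encode desmin and a LIM-domain protein, rose 2.24-fold and 2.57-fold, and Rcan1, a calcineurin target, 2.7-fold. Nppb lies on chromosome 4, 147985786 to 147987205, and Nppa next to it at 148000722 to 148002074. Of these 25 fetal and hypertrophy genes, 16 rose, 1 fell (Myh7b) and 8 were not past the test (19 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 1.36 (camera, adjusted p = 4.0e-15; adjusted p = 0.25 with an estimated correlation). The list median differed from the control mean by 1.28, 1.69 and 0.70 log2 in replicates 6, 7 and 8. With 1 library left out, 10 to 18 of the genes rose, and 11 rose with a robust trend and 8 without a trend. Not past the test without 1 library were Fhl1 (without controls 4 or 5, adjusted p up to 0.056) and Rcan1 (without control 4, adjusted p = 0.053). Fhl1 was also not past the test with a robust trend (adjusted p = 0.067). Myh6 had a log2 fold change of -0.68 ± 0.30 (adjusted p = 0.18), and it was past the test with a robust trend (adjusted p = 0.025), with limma-voom (0.022) and without replicate 8 (7.7e-04).

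**Figure D3:**
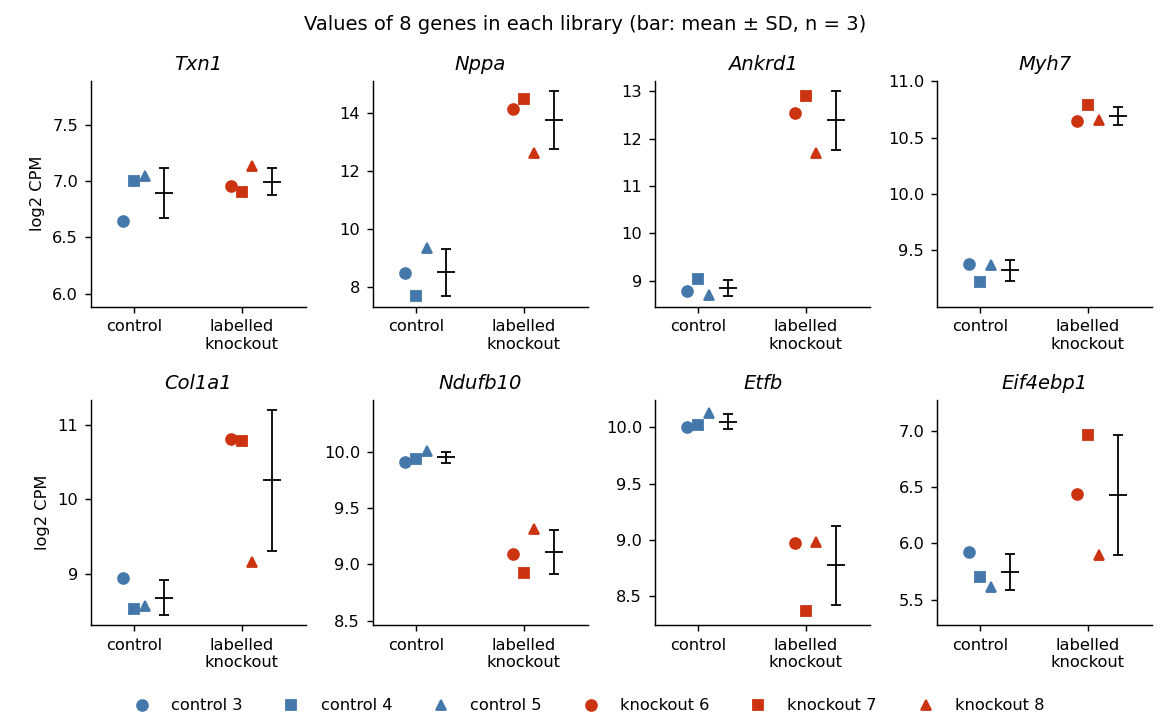
Log2 CPM of 8 genes in each of the 6 libraries, 1 point per library with the mean ± SD of each group of 3 beside the points. Txn1 overlaps between the groups, Nppa, Ankrd1 and Myh7 lie above the controls and Ndufb10 and Etfb below them in all 3 libraries labelled knockout, and replicate 8 lies nearest to the controls for Col1a1 and Eif4ebp1.

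Of 38 tested collagen and other matrix genes, 29 rose. Col1a1 and Col3a1, the genes of the main fibrillar collagens, rose 2.97-fold and 3.13-fold, Postn, a matrix gene of activated fibroblasts, 10.2-fold, and Fn1, fibronectin, 2.66-fold. Timp1, an inhibitor of matrix proteases, rose 8.68-fold, Lox, a collagen cross-linking enzyme, 9.08-fold, Eln, elastin, 6.97-fold, and Tgfb2, a growth factor gene, 4.76-fold. In this list, extracellular matrix and fibrosis, 0 genes fell and 9 were not past the test, and 34 rose when adjusted over the list alone, with a median log2 fold change of 1.76 (camera, adjusted p = 4.4e-27; adjusted p = 0.25 with an estimated correlation). The list median was 2.11, 2.44 and 0.93 log2 above the control mean in replicates 6, 7 and 8, and 21 to 36 genes rose with 1 library left out. With a robust trend 18 of them rose, and without a trend 3 matrix genes and 1 fibroblast marker. Of the 16 tested fibroblast markers, 6 rose and 0 fell, and 6 rose when adjusted over the list alone. Mfap5, Pi16 and Dcn were among them (6.1-fold, 3.32-fold and 1.72-fold), and the median log2 fold change was 0.58 (camera, adjusted p = 7.3e-05; adjusted p = 0.28 with an estimated correlation), with 3 to 7 genes rising with 1 library left out. The fits without 1 library ended the calls of Col1a1 (without controls 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.077) and Col3a1 (without control 4, adjusted p = 0.056). A robust trend also ended the calls of Col1a1, Col3a1 and Postn (adjusted p = 0.12, 0.079 and 0.0704).

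Many nuclear genes of the respiratory chain fell, 67 of 104 tested over 4 lists. Ndufb10, a complex I subunit gene, went from 9.95 ± 0.05 to 9.11 ± 0.19 log2 CPM (SD, n = 3), and Ndufab1 and Ndufa12 fell by 0.91 and 0.75 on the log2 scale. Of the 46 tested complex I genes, 32 fell, 0 rose and 14 were not past the test, and 43 fell when adjusted over the list alone, with a median log2 fold change of -0.57 (camera, adjusted p = 4.4e-22; adjusted p = 0.25 with an estimated correlation). Of the 17 tested genes of complexes II and III, 11 fell and 0 rose (14 fell when adjusted over the list alone), among them Cycs, cytochrome c, by 0.79, Uqcrc1 by 0.76 and Cyc1 by 0.66. Their median was -0.67 (camera, adjusted p = 3.2e-10; adjusted p = 0.25 with an estimated correlation). Of 24 tested genes of complex IV, 10 fell and 0 rose (14 fell when adjusted over the list alone), with the muscle isoforms Cox7a1, Cox8b and Cox6a2 lower by log2 fold changes of -1.07 ± 0.15, -0.94 ± 0.15 and -0.92 ± 0.17 (SE), and the list median was -0.47 (camera, adjusted p = 7.6e-07; adjusted p = 0.25 with an estimated correlation). Of 17 tested ATP synthase genes, 14 fell, Atp5e by 0.83 and Atp5g1 by 0.78, and 1 rose, Atpif1, the gene of the inhibitory factor of the enzyme (0.71 ± 0.15, SE). Adjusted over the list alone, 16 fell and 1 rose, and the median was -0.61 (camera, adjusted p = 4.0e-10; adjusted p = 0.25 with an estimated correlation).

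The 4 list medians lay below the control mean in each library labelled knockout. For complex I they differed by -0.55, -0.72 and -0.40 log2 in replicates 6, 7 and 8. Beside this, the median log2 fold change was -0.61 for adult cardiomyocyte genes, 0.00 for cardiac transcription factors, 0.58 for fibroblast markers and -0.22 for endothelial markers. In the fits without 1 library, 5 to 38 complex I genes fell, 0 to 13 of complexes II and III, 4 to 11 of complex IV and 2 to 16 of ATP synthase. Without a trend in the variance 0 genes of these 4 lists fell, so all 67 calls ended, and after quantile normalization 7 ATP synthase genes fell. Dropping 1 library at a time ended the calls of Cycs (without control 4, adjusted p = 0.068), Uqcrc1 (without controls 4 or 5, adjusted p up to 0.065) and Cyc1 (without controls 3, 4 or 5, adjusted p up to 0.072). Further such genes were Atpif1 (without controls 3 or 4, adjusted p up to 0.088).

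Some genes of fuel oxidation and of the mitochondrial ribosome also fell, 17 of 28 for fatty acid oxidation, 7 of 21 for the TCA cycle and 20 of 72 for the mitochondrial ribosome. Etfb, which passes electrons from fatty acid oxidation to the respiratory chain, fell by 1.27 on the log2 scale, Acaa2 by 1.26, Eci1 by 1.23 and Hadha, the alpha subunit of the trifunctional protein, by 0.89. Of the 28 tested fatty acid oxidation genes, 17 fell, 0 rose and 11 were not past the test (1 rose and 23 fell when adjusted over the list alone), with a median log2 fold change of -0.62 (camera, adjusted p = 3.0e-13; adjusted p = 0.25 with an estimated correlation). Of the 21 tested TCA cycle genes, 7 fell and 0 rose (15 fell when adjusted over the list alone), with Suclg1, Idh3b and Fh1 lower by log2 fold changes of -0.91 ± 0.13, -0.85 ± 0.15 and -0.81 ± 0.16 (SE) and a median of -0.46 (camera, adjusted p = 2.4e-09; adjusted p = 0.37 with an estimated correlation). Fry gave TCA cycle genes an adjusted p of 0.078. Of the 72 tested mitochondrial ribosome genes, 20 fell and 0 rose (29 fell when adjusted over the list alone), among them Mrps35, Mrps31 and Mrpl18 by 1.02, 1.02 and 0.82, and the median was -0.37 (camera, adjusted p = 2.0e-11; adjusted p = 0.25 with an estimated correlation).

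Of the 22 tested regulators of mitochondrial biogenesis, 3 fell and 0 rose, and 5 fell when adjusted over the list alone. They were the nuclear receptor genes Ppara and Esrra (-1.02 ± 0.20 and -0.54 ± 0.16, log2 fold change and SE) and the coactivator gene Ppargc1b (-0.86 ± 0.23). The list median was -0.20 (camera, adjusted p = 0.015; adjusted p = 0.44 with an estimated correlation), and the list was not past the test without replicate 6 (adjusted p = 0.095) or with fry (0.12). Ppargc1a, which encodes a related coactivator, had a log2 fold change of -0.40 ± 0.28 (adjusted p = 0.41), and of 0.028 without replicate 6. When 1 library was dropped, 5 to 20 fatty acid oxidation genes, 2 to 19 TCA cycle genes, 3 to 30 mitochondrial ribosome genes and 0 to 6 biogenesis regulators fell. In the fit without a trend 0 genes of these 4 lists fell, and with library weights 13 TCA cycle genes fell. Leaving out 1 library at a time ended the calls of Fh1 (without controls 4 or 5, adjusted p up to 0.064), Mrpl18 (without controls 3 or 5, adjusted p up to 0.062) and Mrps35 (without controls 3, 4 or 5, adjusted p up to 0.0798). This was also so for Ppara (without control 4, adjusted p = 0.056), Esrra (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.18) and Ppargc1b (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.15). Esrra was also not past the test after quantile normalization (adjusted p = 0.065).

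RNA of mTOR pathway components did not pass the main test in either direction. Of 35 tested components and direct regulators, 0 rose and 0 fell with limma, 0 when adjusted over the list alone and 0 with limma-voom. An unadjusted p under 0.05 was found for 5 of them, against 3098 of all 12516 tested genes. The median log2 fold change was -0.05 (camera, adjusted p = 0.84). The form of fry that counts changes in either direction, also without comparing other genes, gave an adjusted p of 0.0079. Mtor itself had a log2 fold change of 0.33 ± 0.14 (SE, adjusted p = 0.17) and Eif4ebp1, the gene of the translation repressor 4E-BP1, 0.68 ± 0.23 (adjusted p = 0.078). Rragd and Rragc, which encode GTPases that bring mTOR to the lysosome, had 0.69 ± 0.20 and 0.53 ± 0.16 (adjusted p = 0.052 and 0.0597). Eif4ebp1 was past the test in 2 settings, among them without replicate 8 (0.95, adjusted p = 0.0028). Without replicate 6 Mtor was past it (0.46, adjusted p = 0.044), and Rragd was without replicate 6 (adjusted p = 0.021) and in 5 other settings. Leaving out 1 library gave 0 to 2 genes of the mTOR list that rose and 0 to 2 that fell. With all libraries, 1 rose with no filter, quantile normalization, log2(CPM + 1) or a robust trend, and 2 with library weights. These are RNA levels, and the phosphorylation state of the pathway was not measured here. Of the 77 tested cytosolic ribosome genes, 0 rose and 0 fell with limma, 0 when adjusted over the list alone and 0 with limma-voom (8 had an unadjusted p under 0.05), with a median of -0.06 (camera, adjusted p = 0.26), and the list was past the test without replicate 6 (adjusted p = 2.7e-04). Rps2 had -0.50 ± 0.16 and Rpl3 0.42 ± 0.15 (adjusted p = 0.064 and 0.095). Rps2 was past the test in 2 settings, among them without replicate 6 (adjusted p = 0.011), and Rpl3 was without replicate 8 (0.025).

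Of the targets of ATF4, the transcription factor of the integrated stress response, some rose, some fell and most were not past the test. Gdf15, a secreted stress cytokine, rose 7.47-fold, Nupr1 3.93-fold, the amino acid transporter gene Slc7a5 3.22-fold, Ppp1r15a 2.08-fold and the transporter gene Slc38a2 1.54-fold. Cth, a cysteine synthesis enzyme, fell by 2.02 on the log2 scale, Aldh1l2 of mitochondrial folate metabolism by 1.99, the transaminase gene Gpt2 by 1.32 and Vegfa by 0.78. Of 49 tested targets, 5 rose, 4 fell and 40 were not past the test (9 rose and 4 fell when adjusted over the list alone), with a median of 0.33 (camera, adjusted p = 0.0029; adjusted p = 0.25 with an estimated correlation). Atf4 itself had a log2 fold change of 0.30 ± 0.13 (adjusted p = 0.16). With 1 library left out, 3 to 13 targets rose and 1 to 4 fell. With a mean of at least 3, 3 rose and 2 fell, and without a trend 0 and 1. Calls lost without 1 library were those of Slc7a5 (without control 3 or labelled knockout 7, adjusted p up to 0.059), Ppp1r15a (without controls 4 or 5, adjusted p up to 0.061) and Slc38a2 (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.15). The same held for Aldh1l2 (without controls 4 or 5, adjusted p up to 0.075), Cth (without controls 4 or 5 or labelled knockout 7, adjusted p up to 0.12) and Vegfa (without controls 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.12).

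Other stress lists were not past the list test. Of the 16 tested genes of the mitochondrial stress response, the chaperone genes Hspd1 and Hspe1 fell by 0.84 and 0.66 on the log2 scale and 0 rose, also when adjusted over the list alone, with a median of -0.18 (camera, adjusted p = 0.13, and 0.047 without replicate 8). Of 22 tested genes of the ER unfolded protein response, 1 fell, Herpud1, by 0.84, and of 17 tested heat shock genes 1 rose, Hspb7, by 0.76 ± 0.19 (log2, SE), with the same counts when adjusted over the list alone. The list medians were 0.05 and 0.24 (camera, adjusted p = 0.94 and 0.17). Without 1 library at a time, 0 to 4 genes of the mitochondrial stress response fell and 0 to 5 heat shock genes rose. All 4 calls in these 3 lists ended without a trend. Not past the test without 1 library were Hspd1 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.11), Hspe1 (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.11) and Herpud1 (without controls 3, 4 or 5, adjusted p up to 0.12). Further such genes were Hspb7 (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.16).

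Among targets of NRF2, a regulator of antioxidant genes, 10 of 33 rose. Nqo1, a quinone reductase, rose 2.45-fold (from 5.15 ± 0.13 to 6.44 ± 0.18 log2 CPM, SD, n = 3), Gsta4, a glutathione transferase, 1.99-fold, Aox1 2.1-fold, Srxn1, the enzyme that repairs peroxiredoxins, 2.03-fold and the NADPH-forming enzyme Me1 1.67-fold. Of 33 tested NRF2 targets, 10 rose, 1 fell (Ces1d) and 22 were not past the test (12 rose and 1 fell when adjusted over the list alone), with a median of 0.31 (camera, adjusted p = 3.0e-05; adjusted p = 0.25 with an estimated correlation). The list median was 0.34, 0.17 and 0.52 log2 above the control mean in replicates 6, 7 and 8. The list of thioredoxin and glutaredoxin systems also holds other peroxide-removing enzymes and superoxide dismutases. Of its 39 tested genes, 9 rose, 1 fell and 29 were not past the test (11 rose and 1 fell when adjusted over the list alone), with a median of 0.11 (camera, adjusted p = 0.098, and 0.019 with fry). Txnrd1, the cytosolic thioredoxin reductase, rose 1.63-fold, and the peroxide-removing enzymes Gpx3, Gpx1 and Cat and the extracellular superoxide dismutase Sod3 rose 3.68-fold, 1.96-fold, 1.81-fold and 2.59-fold. The gene that fell was Sod2, the mitochondrial superoxide dismutase, by 0.59 on the log2 scale. The mitochondrial thioredoxin Txn2 and its reductase Txnrd2 had -0.34 ± 0.15 and -0.24 ± 0.16 (adjusted p = 0.17 and 0.38). In the fits without 1 library, 5 to 11 NRF2 targets and 3 to 12 genes of the thioredoxin and glutaredoxin list rose. Without a trend 2 and 0 rose. The fits without 1 library ended the calls of Srxn1 (without controls 3 or 5 or labelled knockout 6, adjusted p up to 0.098), Txnrd1 (without controls 3 or 5, adjusted p up to 0.086) and Cat (without control 5, adjusted p = 0.052). This was also so for Sod2 (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.11).

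Among adult cardiomyocyte genes 12 of 35 fell. Hcn4, the pacemaker channel, fell by 2.30 on the log2 scale, the potassium channel gene Kcnj2 by 1.54 and Tnni3, cardiac troponin I, by 1.01. Of 35 tested genes, 12 fell, 0 rose and 23 were not past the test (1 rose and 18 fell when adjusted over the list alone), with a median of -0.61 (camera, adjusted p = 6.9e-07; adjusted p = 0.33 with an estimated correlation). When 1 library was dropped, 3 to 20 fell, and 1 without a trend. Of 19 tested cardiac transcription factors, Tbx20 and Nkx2-5 rose (0.75 ± 0.16 and 0.62 ± 0.17, log2 and SE) and Hopx fell by 0.89 (2 rose and 2 fell when adjusted over the list alone), with a median of 0.00 (camera, adjusted p = 0.53). Of 9 tested atrial genes, Myl7 and Stard10 fell by 2.53 and 2.02 and Dkk3 rose 2.34-fold (1 rose and 4 fell when adjusted over the list alone), with a median of -0.86 (camera, adjusted p = 0.037; adjusted p = 0.43 with an estimated correlation). The atrial list was not past the test without control replicate 5, replicate 6 or replicate 7 (adjusted p = 0.085, 0.12 and 0.053), with a mean of at least 3 (0.11), without a trend (0.057) or with fry (0.15). Of 6 tested skeletal muscle markers, Acta1 and Tnnt3 rose and Ckm, the muscle creatine kinase, fell by 0.98 (2 rose and 2 fell when adjusted over the list alone), with a median of -0.16, a mean of 0.39 and a test that pointed up (camera, adjusted p = 0.70). Without 1 library at a time, 0 to 3 cardiac transcription factors rose, 1 to 4 atrial genes fell and 0 to 2 skeletal muscle markers fell. With library weights 4 atrial genes fell, and without a trend 0. Dropping 1 library at a time ended the calls of Tnni3 (without control 5, adjusted p = 0.0598), Tbx20 (without controls 3, 4 or 5, adjusted p up to 0.084) and Nkx2-5 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.17). The same held for Hopx (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.15), Myl7 (without controls 3 or 5 or labelled knockout 6 or 7, adjusted p up to 0.14) and Dkk3 (without controls 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.092). Further such genes were Tnnt3 (without controls 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.071) and Ckm (without controls 3, 4 or 5, adjusted p up to 0.082). Nkx2-5 was not past the test after quantile normalization (adjusted p = 0.055), nor Myl7 with a robust trend (0.21).

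Markers of the other cell types of the heart did not move as 1 group. Among 20 tested endothelial markers, Vwf rose 1.52-fold and Kdr, a VEGF receptor, fell by 1.07 on the log2 scale, the same 1 and 1 when adjusted over the list alone, with a median of -0.22 (camera, adjusted p = 0.055, and 0.041 without control replicate 5 and 0.0202 without replicate 8). With no filter on low values or with library weights the endothelial list was also past it (adjusted p = 0.036 and 0.034). Among 14 tested smooth muscle and pericyte markers, Des and Cspg4 rose (1.16 ± 0.20 and 0.83 ± 0.19, log2 and SE) and Smtn and Abcc9 fell by 0.99 and 0.85 (4 rose and 2 fell when adjusted over the list alone), with a median of 0.03 (camera, adjusted p = 0.62). Des is also a gene of cardiomyocytes. Of 21 tested macrophage markers, Itgam rose 1.96-fold, also when adjusted over the list alone, and 20 were not past the test, with a median of 0.24 (camera, adjusted p = 0.014; adjusted p = 0.25 with an estimated correlation). That list was not past the test without control replicate 3 (adjusted p = 0.055).

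No member of the lymphocyte, neutrophil or erythroid lists was past the limma test, of 8, 4 and 7 tested, nor with limma-voom. Adjusted over the list alone 0, 1 and 0 rose and 0 fell, and 0, 1 and 1 had an unadjusted p under 0.05. The lowest p belonged to Il7r, Lcn2 and Car2, with log2 fold changes of 1.01 ± 0.47, 1.54 ± 0.51 and -0.96 ± 0.41 (SE), and Car2 was past the test without replicate 8 (adjusted p = 0.046). The medians were -0.11, 0.77 and -0.17 (camera, adjusted p = 0.98, 0.401 and 0.32), and the lymphocyte list had a mean of 0.03. Among 4 tested adipocyte markers, Cidea, a lipid droplet gene also seen in brown fat, rose 1.84-fold and Cfd, an adipokine gene, fell by 3.09 on the log2 scale (1 rose and 2 fell when adjusted over the list alone), with a median of -0.44 (camera, adjusted p = 0.71, and 0.025 with no filter on low values). Among 6 tested markers of epicardium and nerve, the mesothelial gene Msln rose 4.64-fold (1 rose and 0 fell when adjusted over the list alone), with a median of -0.06, a mean of 0.10 and a test that pointed up (camera, adjusted p = 0.94). Without 1 library at a time, 0 to 5 endothelial and 0 to 2 adipocyte markers fell, and 0 to 1 macrophage markers rose. Library weights gave 3 endothelial markers that fell, and without a trend no member of the cell type lists of endothelium, smooth muscle, macrophages, adipocytes or epicardium and nerve was past the test. Leaving out 1 library at a time ended the calls of Vwf (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.19), Kdr (without control 5, adjusted p = 0.052) and Cspg4 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.096). Further such genes were Abcc9 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.11), Itgam (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.12) and Cidea (without controls 4 or 5, adjusted p up to 0.059). This was also so for Cfd (without controls 3 or 5 or labelled knockout 7, adjusted p up to 0.196) and Msln (without controls 4 or 5 or labelled knockout 6, 7 or 8, adjusted p up to 0.14). Cfd was also not past the test with limma-voom or a robust trend (adjusted p = 0.0904 and 0.0505), nor Msln with library weights (0.076).

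Among genes of autophagy and lysosomes 6 of 37 rose. Sqstm1, the autophagy receptor p62, rose 1.87-fold, Atg13, an initiation factor of autophagy, 2.11-fold and the lysosomal proteases Ctsd and Ctsl 1.6-fold and 1.55-fold. Of 37 tested genes, 6 rose and 0 fell, also when adjusted over the list alone, with a median of 0.26 (camera, adjusted p = 1.7e-04; adjusted p = 0.25 with an estimated correlation). Of 35 tested proteasome genes and atrogenes, 0 rose and 0 fell with limma, with limma-voom and when adjusted over the list alone (10 had an unadjusted p under 0.05), with a median of 0.12 (camera, adjusted p = 0.015; adjusted p = 0.63 with an estimated correlation). That list was not past the test without control replicate 3 or replicate 7 (adjusted p = 0.055 and 0.15) or with fry (0.26). Psmc1, a proteasome ATPase, and Fbxo32, the ubiquitin ligase atrogin-1, had 0.48 ± 0.14 and 0.69 ± 0.22 (adjusted p = 0.055 and 0.0697), and both were past the test without replicate 8 (0.011 and 0.039). Psmc1 was also past it after quantile normalization and with library weights (0.034 and 0.026). With 1 library left out, 2 to 9 autophagy and lysosome genes and 0 to 8 proteasome genes and atrogenes rose, and without a trend 0 and 0. Calls lost without 1 library were those of Ctsd (without controls 3, 4 or 5, adjusted p up to 0.064) and Ctsl (without controls 3, 4 or 5, adjusted p up to 0.064).

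Of 21 tested p53 targets, 4 rose and 0 fell (5 rose and 1 fell when adjusted over the list alone), with a median of 0.40 (camera, adjusted p = 0.047; adjusted p = 0.25 with an estimated correlation). They were Phlda3, Zmat3, Perp and the cell cycle inhibitor Cdkn1a (3.23-fold, 2.81-fold, 1.95-fold and 2.32-fold). The list was past the test without control replicate 3 but with no other library left out (adjusted p = 0.053 to 0.095), nor after quantile normalization (0.053), with library weights (0.057), with limma-voom (0.053) or with a mean of at least 3 (0.12). Of 24 tested cell death genes 1 rose, Casp12 (1.26 ± 0.31, log2 and SE), and of 31 tested cell cycle genes the mitotic motor gene Kif11 rose (2.30 ± 0.59) and Cenpf, a kinetochore gene, fell by 1.69. Adjusted over the list alone, 3 cell death genes rose and 0 fell, and 1 cell cycle gene rose and 1 fell. The medians were 0.04 and 0.38 (camera, adjusted p = 0.13 and 0.46), and fry gave cell death genes an adjusted p of 0.019. Across the 6 fits without 1 library, 0 to 4 p53 targets, 0 to 4 cell death genes and 0 to 2 cell cycle genes rose, and without a trend 1, 0 and 0. Not past the test without 1 library were Phlda3 (without control 4, adjusted p = 0.065), Zmat3 (without controls 3, 4 or 5 or labelled knockout 6, 7 or 8, adjusted p up to 0.14) and Perp (without control 4, adjusted p = 0.053). The same held for Cdkn1a (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.15), Casp12 (without controls 3 or 4 or labelled knockout 7, adjusted p up to 0.11) and Kif11 (without controls 3 or 5 or labelled knockout 6 or 7, adjusted p up to 0.14).

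Of the tested glycolysis genes some rose, some fell and most were not past the test. The hexokinase gene Hk1 rose 2.08-fold (from 8.11 ± 0.09 to 9.16 ± 0.15 log2 CPM, SD, n = 3) while Hk2, the form of adult muscle, fell by 0.91 on the log2 scale. The glucose transporter gene Slc2a1 rose 2.12-fold while Slc2a4, the insulin-responsive form, fell by 0.99, and Pfkp rose 1.99-fold while Pfkm, the muscle phosphofructokinase, fell by 0.71. Slc16a3, a lactate transporter gene, rose 2.41-fold, and the muscle enolase Eno3 fell by 1.24. Of 27 tested glycolysis genes, 4 rose, 4 fell and 19 were not past the test (7 rose and 8 fell when adjusted over the list alone), with a median of -0.06 and a mean of 0.00, and a test that pointed up (camera, adjusted p = 0.98). Of 20 tested hypoxia genes, Slc2a1 rose and Hk2, Vegfa and Egln3 fell (3 rose and 3 fell when adjusted over the list alone), with a median of 0.02 (camera, adjusted p = 0.76). Of 31 tested genes of cholesterol and lipid synthesis, Fdft1 and Acacb fell by 0.70 and 0.51 and 0 rose (0 rose and 1 fell when adjusted over the list alone), with a median of -0.13 (camera, adjusted p = 0.47). Across the fits without 1 library, 2 to 6 glycolysis genes rose and 2 to 7 fell, 1 to 3 hypoxia genes fell, and 0 to 2 genes of cholesterol and lipid synthesis fell. With library weights 7 glycolysis genes fell, and without a trend 1 rose and 0 fell. The fits without 1 library ended the calls of Slc2a4 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.088), Pfkp (without control 5, adjusted p = 0.054) and Pfkm (without controls 3, 4 or 5, adjusted p up to 0.087). Further such genes were Slc16a3 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.12), Egln3 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.18) and Vegfa (without controls 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.12). This was also so for Fdft1 (without controls 3, 4 or 5, adjusted p up to 0.082) and Acacb (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.19). Pfkm and Acacb were also not past it after quantile normalization (adjusted p = 0.065 and 0.072).

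A few inflammation genes rose and a few interferon genes fell, and the 2 lists were not tested against each other. Ptx3, an acute-phase pattern recognition gene, rose 6.64-fold from -0.17 ± 0.91 log2 CPM, Osmr, the oncostatin M receptor, 2.21-fold and the adhesion gene Vcam1 1.66-fold. Of 22 tested inflammation genes, 3 rose and 0 fell (5 rose and 0 fell when adjusted over the list alone), with a median of 0.32 (camera, adjusted p = 2.5e-04; adjusted p = 0.25 with an estimated correlation). Rsad2 and Oas2 fell by 0.97 and 1.23 on the log2 scale. Of 24 tested interferon genes 3 fell and 0 rose, also when adjusted over the list alone, with a median of -0.38 (camera, adjusted p = 0.014; adjusted p = 0.54 with an estimated correlation). That list was not past the test without control replicate 3 or replicate 7 (adjusted p = 0.092 and 0.084) or with fry (0.21). Of 22 tested immediate early genes, Myc and Junb rose 2.41-fold and 1.84-fold and 0 fell (3 rose and 0 fell when adjusted over the list alone), with a median of 0.30 (camera, adjusted p = 0.011; adjusted p = 0.25 with an estimated correlation). With a mean of at least 3 that list was not past the test (adjusted p = 0.080). Across the fits without 1 library, 1 to 3 inflammation genes and 0 to 5 immediate early genes rose and 0 to 6 interferon genes fell. All calls in these 3 lists ended without a trend. Dropping 1 library at a time ended the calls of Ptx3 (without labelled knockout 7, adjusted p = 0.0597), Vcam1 (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.15) and Rsad2 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.11). This was also so for Oas2 (without controls 3, 4 or 5 or labelled knockout 7, adjusted p up to 0.12), Myc (without controls 3, 4 or 5 or labelled knockout 6, adjusted p up to 0.098) and Junb (without controls 4 or 5 or labelled knockout 6, adjusted p up to 0.15).

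Of the tested clock genes 2 rose and 4 fell, while 13 were not past the test. Arntl, the gene of the clock activator BMAL1, rose 10.5-fold (from 0.08 ± 0.90 to 3.47 ± 1.13 log2 CPM, SD, n = 3) and Npas2, its partner, 4.28-fold. Hlf, Dbp, Per3 and Tef, whose RNA peaks at another time of day, fell by 2.09, 1.49, 1.34 and 0.74 on the log2 scale. The 19 clock genes (3 rose and 5 fell when adjusted over the list alone) had a median of -0.12 (camera, adjusted p = 0.43, and 0.033 without replicate 7). The labels used here give no time of collection. Across the fits without 1 library, 1 to 2 clock genes rose and 2 to 5 fell, and without a trend 0 rose and 1 fell. Leaving out 1 library at a time ended the calls of Npas2 (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.14), Per3 (without controls 4 or 5, adjusted p up to 0.069) and Tef (without controls 3, 4 or 5 or labelled knockout 6 or 7, adjusted p up to 0.19). Npas2 was also not past it with library weights (adjusted p = 0.055).

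**Figure D4:**
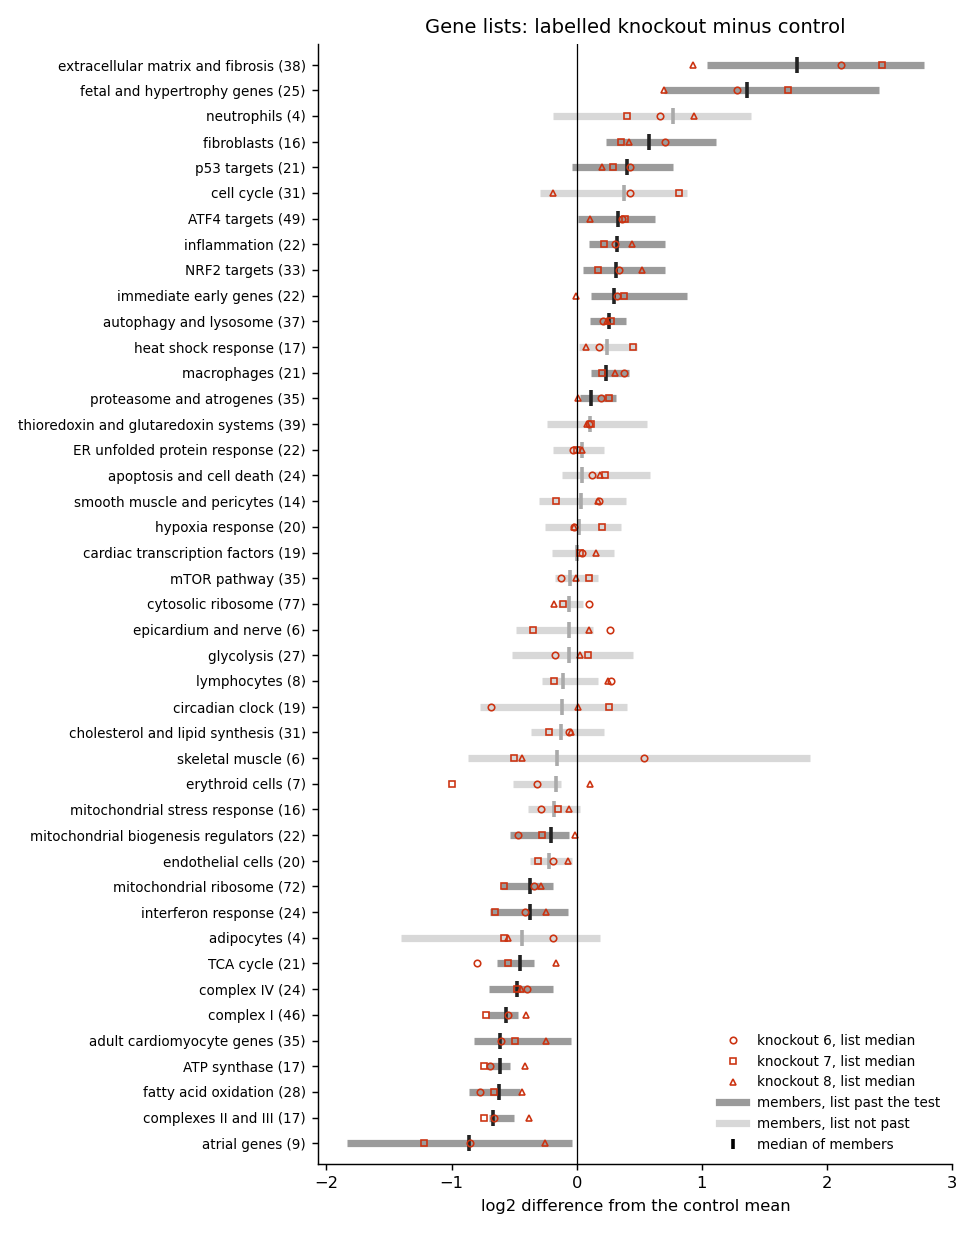
Log2 difference from the control mean for the 43 gene lists, with the number of tested genes in brackets. Bars span the log2 fold changes of the members from the lower to the upper quartile and the tick marks their median, dark where the list was past the camera test with the preset correlation, and open red symbols give the list median in each library labelled knockout. The matrix and fetal lists lie highest, the lists of mitochondrial complexes lie below 0 in all 3 libraries, and replicate 8 lies nearer to 0 than replicates 6 and 7 in both of the highest lists.

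In all, camera with its preset correlation called 11 lists up and 11 down of 43. With an estimated correlation it called 0, at a smallest adjusted p of 0.25, and 6 lists had an unadjusted p under 0.05. The preset p-values take a correlation of 0.01 within every list. The estimates ranged from -0.034 (cell death) to 0.89 (TCA cycle), with 0.71 for the matrix list and 0.46 for complex I. Because the control hearts carried no Cre, an effect of Cre is not separated from that of recombination of the floxed alleles.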

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

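Of the tests in this part, only that of reads spread over the genome was chosen before its result was seen, and all others were chosen after. The 1617 genes left out by the filter on low values were not among the 12516 tested genes. Their reads made up a larger share of all reads in each library labelled knockout than in the controls. They came to 1790 RPM (reads scaled to all reads of the library) in replicate 6, 1012 in replicate 7 and 922 in replicate 8, against 875 to 906 in the controls. The excess of replicate 8 over the highest control, replicate 3, is small and depends on the scale. The deposited CPM use a library size of 8.58 M for replicate 8, against 8.35 M reads. For control replicate 3 they use 13.5 M, against 13.7 M reads. Scaled to these sizes, replicate 8 lies below control replicate 3.

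In replicate 6, 1431 of these genes had a read, against 1173 to 1256 in the controls, 1241 in replicate 7 and 1111 in replicate 8. Reads spread evenly over the genome would follow exon length. Across 210 genes low in the other 5 libraries, Spearman's rho of its reads with exon length was -0.00128. It was -0.066 to 0.14 in the other libraries, and genes are not independent replicates. The 210 genes had a median of 8.75 reads in replicate 6, and only 5 genes of the table lay at the floor in all 6 libraries. Genes without reads may have been left out before deposit, so the 210 genes may be there because of their reads in replicate 6. The test therefore does not decide on spread reads. Greater depth is argued against by its 8.96 M reads, fewer than in every control library. RNA from other cells in this heart stays open as an untested source.

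Many respiratory chain genes fell (67 of 104) while many matrix genes rose (29 of 38). A lower share of cardiomyocyte RNA, with the other cell types in fixed proportion, would raise the markers of all of these alike. The lower quartile of the fibroblast log2 fold changes lay 0.28 above the upper quartile of the endothelial ones, so these did not move alike. A higher share of fibroblasts would give the same gap and stays open. The test therefore does not decide whether a lower share of cardiomyocyte RNA lowered the respiratory chain genes. The median log2 fold change was -0.61 for adult cardiomyocyte genes, 0.00 for cardiac transcription factors and -0.57 for complex I genes. For the scaling of the libraries, a first test, the share of the respiratory chain genes that fell still past the test after quantile normalization, did not decide, with 48 of 67 (71.6%) between its bounds of 20% and 80%. A second test was chosen after that: the upper quartile of all 104 members was -0.46 before quantile normalization and -0.38 after it (median -0.57 and -0.54). The median over all tested genes was already -0.01, so this test could hardly have brought the quartile to 0. It shows that the members stayed low relative to other genes, and it does not decide on scaling. An effect of Cre itself cannot be told apart from that of recombination of the floxed alleles, which both groups carry, since 0 control libraries carried Cre, and with Txn1 RNA not lower, loss of Txn1 and a wrong label both stay open as untested.

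Arntl and Npas2 rose while Dbp, Hlf, Per3 and Tef fell. Another time of collection could produce this, but the labels used here give no times, and Nr1d1, which peaks opposite to Arntl, had a log2 fold change of -0.35 (adjusted p = 0.25, and 0.037 without replicate 7, with -0.57). The time of collection and the group therefore cannot be told apart, and a biological change of the clock was not tested separately.

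The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1209 genes and the highest other 1, and 1 split gave as many genes. The other splits mix the groups, so the difference between the groups adds to their spread. Few genes past the test were bound to follow, and these gene counts do not show what chance gives. The real split gave 22 lists and the highest other 19, and 1 split gave as many lists. Camera with its preset correlation thus called many lists in splits that mix the groups.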

How the results depend on the processing

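In this part only limma-voom was chosen after seeing the data. edgeR and DESeq2 were planned only for a table of raw counts. The table holds log2 CPM, so they were not run, and of the count methods only limma-voom was applied to the recovered reads. No paired analysis was possible because the replicate numbers, 3 to 5 and 6 to 8, are shared by no pair of libraries. With 1 library left out, its group keeps 2 libraries.

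The count of genes, 1209 with 600 that rose and 609 that fell, stayed within 1.5 times in the other settings except 2. It was 121 (71 rose and 50 fell) without a trend, where the cause was not tested, and 432 (230 and 202) at an adjusted p under 0.01, a stricter threshold. With 1 library left out it ranged from 403 (242 rose and 161 fell, without control replicate 4) to 2185 (1010 and 1175, without replicate 8). Each of these fits has 1 library fewer, and each takes the same spread for both groups. The spreads differed. Fitted library weights, lower for more variable libraries, were 1.42 to 1.97 in the controls and 0.56 to 0.66 in the others. Without a control, the more variable group makes up more of the estimated spread. How far this accounts for the lower counts was not tested. The rise without replicate 8 goes with the smaller shifts of that library. No gene called both in all libraries and under any of the 15 refits changed direction. Of the 231 genes of the rule, 168 were past the test, of which 0 turned direction and 143 lost the call in some setting. Of the 63 others 9 turned direction. Of the 146 named genes past the test, 120 were no longer past it without a trend, 8 with a robust trend, 4 after quantile normalization, 2 with library weights and 1 with limma-voom.

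The 11 lists up and 11 down became 0 and 0 with an estimated correlation. That setting replaced the preset 0.01 by estimates of up to 0.89 (TCA cycle). Calls also ended where the estimate was low, as for ATF4 targets (0.024). With fry 7 lists were down. The causes were not tested separately. Txn1 ranged from -0.025 (without control replicate 3) to 0.18 (without control replicate 5), and Ppargc1a from -0.65 (without replicate 8) to 0.028 (without replicate 6), where its direction turned. Myh6 was the highest gene in every library, so quantile normalization sets its difference to 0.

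Lists whose direction turned were not past the test in that setting. They were cell cycle with a mean of at least 3 (adjusted p = 0.11), and glycolysis with library weights (0.99), limma-voom (0.997), and without control replicate 3 (0.87), replicate 7 (0.83) or replicate 8 (0.64). Hypoxia turned without control replicate 3 (0.96) or replicate 7 (0.91), mTOR without control replicate 5 (0.96) or replicate 7 (0.76), and lymphocytes in the same fits (0.79 and 0.73). The ER unfolded protein response turned without control replicate 5 (0.79), and the cytosolic ribosome without replicate 8 (0.97). Without replicate 6 epicardium and nerve (0.92), skeletal muscle (0.93) and the clock (0.92) turned. The cause was not tested. Over the fits without 1 library the adjusted p ranged as follows: mTOR pathway 0.33 to 0.96, ER unfolded protein response 0.78 to 0.97, lymphocytes 0.73 to 0.98, epicardium and nerve 0.76 to 0.997, skeletal muscle 0.41 to 0.93, glycolysis 0.52 to 0.96, circadian clock 0.033 to 0.92, hypoxia response 0.41 to 0.96 and cytosolic ribosome 2.7e-04 to 0.97.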

Other observations

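All observations in this part were chosen after the values were seen. Morf4l1b, on chromosome 19, 41525252 to 41526961, had 1, 0 and 0 reads in the controls and 95, 474 and 435 in replicates 6, 7 and 8 (limma, adjusted p = 8.2e-05). Morf4l1, the related gene on chromosome 9, had a log2 fold change of -0.06 (adjusted p = 0.85).

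Between 30000001 and 35000000 of chromosome 13, 10 of 25 tested genes were past the test, the highest share among 229 stretches of 5 megabases with at least 20 tested genes. In 72 of 10000 permutations of the calls among tested genes a stretch was as high (permutation p = 0.0073), which takes neighbouring genes as unrelated. Serpinb1c, Serpinb6b, Serpinb9b and Serpinb6a, and Tubb2a and Tubb2b, are 2 families whose reads can be shared, and they rose, from 0.91 (Serpinb6a) to 3.66 (Serpinb1c) in log2 fold change. Reads were few for Serpinb1c, with 19, 0 and 4 in controls 3, 4 and 5 and 86, 97 and 15 in replicates 6, 7 and 8. For Serpinb9b they were 5, 2 and 6, and 43, 49 and 16. Agtr1a fell by 1.02 on the log2 scale, Uqcrfs1 fell by 0.74, Mylk4 fell by 2.82 and Eci2 fell by 0.55. Within 5 megabases of Txn1, 6 of 35 tested genes were past the test (17.1%, against 9.67% of all tested genes with a position, 1-sided Fisher's exact test p = 0.12), a count not beyond chance in a test added after it was seen.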
